A study of Mus musculus with 23 samples.

How the data were processed

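Messenger RNA levels were measured in 23 samples of circumvallate papilla from male C57Bl6/j mice. Per the series' design text, lingual epithelium was freed from the connective tissue beneath it with enzymes and the papilla was then dissected under a microscope. Per the labels' protocols, labelled copy RNA was made from 25 ng of total RNA of each sample and hybridised to a 1-colour Agilent mouse array. Each array carries 62976 spots, of which 3671 are controls, for 55681 distinct probes besides the controls. The deposited scanner intensity of each spot was produced with Agilent Feature Extraction 10.10.1.1, per the file headers, which subtracts background and a spatial trend within an array and sets nothing equal between arrays. The headers give mouse build mm9 for the probe positions, and those positions are printed as the headers' annotation gives them. No array showed a saturated spot, and between 66.9% and 78.4% of the probes of an array were well above background. Arrays carry no read depth; their number, 7 or 8 in a group, limits the precision.

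The samples were grouped by the condition named in their labels into Lean (n = 7), DIO (n = 8) and DIO-R (n = 8). DIO-R is not defined in the labels and is read here as the DIO mice whose energy intake was restricted to 60% of that taken freely. Nothing in the labels says how long the diets lasted, at what hour the tissue was taken, or that each sample is a separate animal. The p-values therefore measure the spread between these samples, which can in part be technical. The arrays lie on 3 slides with 8, 8 and 7 arrays, and each slide holds every group. The scan batch is identical to the slide, so the scan date was not tried as a separate term. Of the genes kept, 202 differed between slides at an adjusted p under 0.05, which is 0.716% of them. The first principal component held 17.8% of the variance, and correlations between pairs of arrays over genes lay between 0.960 and 0.991, so no pair was treated as 1 sample.

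The values analysed were log2 of the background-subtracted intensity minus the 75th percentile of the same array over its spots that are not controls. Spots marked as outliers by the scanner software were left out, and spots of one probe were averaged. A gene was represented by its probe with the highest mean over all arrays and was kept if that probe was well above background on at least 7 of the 23 arrays. This left 28209 genes of 34797 symbols on the array, 28196 of them with a value on every array. Symbols are those of the array's design, updated through a RefSeq table of assembly GRCm38.p6 where the accession matched; 17300 genes matched and 1796 changed their symbol. Exon and untranslated region boundaries of build mm9 were not used here. Near-identical gene copies, such as the haemoglobin beta genes and Acot1 with Acot2, can share probe signal and their values are uncertain to that extent.

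The deposited value table of the authors holds 35829 probes on a log2 scale. The labels do not state how it was made beyond naming limma, per the submitters' processing notes. Its columns ranked the probes almost exactly as the scanner's median spot intensity without background subtraction (lowest Spearman correlation 0.999991), against 0.998 to 0.999 for the background-subtracted intensity. Its array medians all lay between 7.63 and 7.64, so the arrays had been brought to a common level. Its exact normalization steps stay unknown, and it was used as an alternative.

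Differences between groups were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) in a fit of all 23 arrays with a mean per group and no covariate. Benjamini-Hochberg adjustment ran over the genes kept, and a gene passed at an adjusted p under 0.05. The R package data.table, version 1.17.8, read the files, and plots were drawn with Python 3.11.15 and matplotlib 3.10.9. A fold given for a gene that fell is the size of the fall. Where a probe was not well above background on any array of a group, the fold is a lower bound, "at least", which sets the brighter group's mean against the array's lowest signal well above background.

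A set of 37 gene lists was written before the data were examined, with 826 genes, of which 779 were kept. They are type II taste cell transduction, bitter taste receptors, type III taste cell genes, type I taste cell genes, fatty acid sensing, taste bud renewal, and taste cell peptides and receptors; proinflammatory cytokines and NF-kB targets, epithelial antimicrobial and alarmin genes, interferon response, MHC class II antigen presentation, and markers of macrophages and dendritic cells, lymphocytes, and neutrophils and mast cells. Further lists are cholesterol synthesis, fatty acid synthesis, PPAR targets and fatty acid oxidation, glucose uptake and glycolysis, respiratory chain subunits, the Bmal1 arm and the Per-Dbp arm of the circadian clock, glucocorticoid response, unfolded protein response, heat shock response, immediate early genes, oxidative stress and xenobiotic response, cell cycle, and ribosomal proteins. The last group holds markers of cells and tissues that a dissected papilla can contain, namely basal keratinocytes, differentiated lingual keratinocytes, von Ebner gland and salivary tissue, skeletal muscle, adipocytes, fibroblasts and extracellular matrix, endothelium and smooth muscle, nerve and Schwann cells, and erythrocytes. Lists were tested with limma's camera at its preset correlation of 0.01, adjusted over the 37 lists, against camera with an estimated correlation and limma's fry as alternatives. The correlations estimated between members of a list had a median of 0.319 and reached 0.807, far above the preset value. A list's score on an array is the mean over its members of the deviation from the gene's mean over all arrays.

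The genes named were chosen by a rule fixed beforehand. In each comparison it takes the 10 largest rises and the 10 largest falls among genes that passed and carry a proper symbol on the array. It adds up to 4 members of each called list by smallest p, and the genes of smallest p, up to 5 in a direction, where fewer than 5 passed. A panel of 14 taste, fat sensing and hormone receptor genes was to be named whatever its values. The whole panel is given for DIO against Lean and a part of it for the other comparisons. After the data were seen, the number of members was set to 3 for the 6 called lists of smallest p and 1 for the rest, to keep the text readable. Genes named outside this rule are said to have been chosen after their values were seen.

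The fit was tested on simulated data with the real genes' means and spreads, over all 28209 genes, with 67, 67 and 66 genes changed 1.5-fold, 2-fold and 4-fold. For DIO against Lean it recovered 52.2%, 79.1% and 93.9% of them. For DIO-R against DIO the shares were 46.3%, 77.6% and 90.9%. For DIO-R against Lean they were 44.8%, 65.7% and 90.9%. Calls among genes simulated as unchanged numbered 10 of 203, 15 of 172 and 6 of 154. The real comparisons called 1, 17 and 36 genes. With fewer calls the Benjamini-Hochberg cut on p is stricter, so the recovered shares overstate what the fit can find in the real data. All 4 lists shifted by 0.5 on the log2 scale were called in each comparison and none of the others, but the simulated genes were independent within lists.

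Alternatives planned beforehand were quantile normalization, normexp background correction with an offset of 50, the authors' value table, stricter and absent filters on dim probes, the mean of a gene's probes, every probe on its own, outlier spots kept, the slide as a block, each slide alone, the replicate number as a block, only the groups compared, array weights, eBayes with trend and robust settings, and each array left out in turn. Alternatives added after seeing the data used as covariates the scores of muscle, adipocyte and gland lists together, of keratinocyte and fibroblast lists together, or of the erythrocyte list, and left out the 2 DIO arrays lowest in taste cell lists. Correlations of fold changes and shared calls were set beside 100 simulations of unchanged groups with the same shared arrays and beside 70 splits of the shared arrays.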

Results

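Messenger RNA was measured in 23 samples of circumvallate papilla, the large taste papilla at the back of the mouse tongue, on 1-colour Agilent arrays. The 7 Lean samples came from male mice fed a standard chow with 3% fat by weight, and the 8 DIO samples from male mice fed an obesogenic diet rich in saturated fat. The 8 DIO-R samples are read as DIO mice held to 60% of freely taken energy, a reading the labels do not spell out. Each of the 28209 genes kept was compared between the groups in a single limma fit. The 3 comparisons ask what the diet group differed in from Lean, what the restricted group differed in from DIO, and what still separated it from Lean.

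DIO against Lean was led by a macrophage gene. Aif1, which encodes a calcium-binding protein of macrophages (probe on chromosome 17, positions 35307959 to 35308018), rose 1.93-fold in DIO (log2 difference 0.95 ± 0.13 SE, n = 8 and 7, adjusted p = 0.00774) and lay above the Lean mean in 8 of 8 DIO samples. As groups, MHC class II, interferon response and cell cycle genes rose and cholesterol synthesis and differentiated keratinocyte genes fell by the list test, calls that were lost with an estimated correlation (adjusted p = 0.106, 0.137, 0.133, 0.136 and 0.299). Aif1 was the 1 gene of 28209 that passed, while 2527 genes had an unadjusted p under 0.05 against 1410 expected by chance. With the slide as a block Aif1 differed by 0.94 (adjusted p = 0.00321), and within slides 1, 2 and 3 by 0.98, 1.01 and 0.81. Its call was lost with the erythrocyte score as a covariate, chosen after the data were seen (1.03, adjusted p = 0.0593), and with the replicate number as a block (0.89, adjusted p = 0.613).

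Among genes that did not pass, Dbp, a transcription factor driven by the circadian clock, was 1.51 ± 0.26 SE higher in DIO (adjusted p = 0.0792). Slamf9 and Tlr12, receptors of immune cells, differed by 0.54 ± 0.10 SE and 0.86 ± 0.16 SE, and the interferon-inducible Ifi203 by 0.89 ± 0.16 SE, each with an adjusted p of 0.0792. On the lower side were Adh1, an alcohol dehydrogenase (-0.67 ± 0.13 SE), and Zranb1, a deubiquitinase (-0.37 ± 0.07 SE), each with an adjusted p of 0.0888. Il22ra2, a soluble binding protein for interleukin 22, differed by -1.55 ± 0.32 SE (adjusted p = 0.0975). Npc1, which exports cholesterol from lysosomes, and Mvd, an enzyme of cholesterol synthesis, differed by -0.34 ± 0.07 SE and -0.65 ± 0.14 SE, each with an adjusted p of 0.11.

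The interferon response list rose in DIO, with 33 of 34 members higher and a median log2 difference of 0.66 (camera adjusted p = 1.04e-20; adjusted p = 0.137 with an estimated correlation). None of its members passed over all genes and 7 did when adjusted over the list alone; Gbp3, a guanylate-binding protein, differed by 1.21 ± 0.29 SE (adjusted p = 0.168) and Ifi27l2a by 1.00 ± 0.26 SE. The MHC class II list rose with 11 of 11 members higher and a median of 0.56 (adjusted p = 2.81e-11; adjusted p = 0.106 with an estimated correlation), 9 of them past the threshold adjusted over the list alone. Its antigen-presenting chains H2-Ab1 and H2-Eb1 differed by 0.64 ± 0.18 SE and 0.66 ± 0.20 SE. Macrophage and dendritic cell markers rose by a median of 0.24 with 16 of 20 higher (adjusted p = 3.74e-07; adjusted p = 0.185 with an estimated correlation). The neutrophil and mast cell list rose by a median of 0.21 (adjusted p = 0.0456; adjusted p = 0.185 with an estimated correlation), with the mast cell protease Mcpt4 at 1.31 ± 0.53 SE. It passed in 5 of 17 settings, was lost without DIO 1, 2, 6 or 10 or Lean 3, 4, 7, 9 or 10, and lay at 0.09 without DIO 10. Beside these immune groups, erythrocyte markers rose with 8 of 8 higher and a median of 1.13 (adjusted p = 2.81e-11; adjusted p = 0.0829 with an estimated correlation), and Hbb-bt, a haemoglobin chain, differed by 1.41 ± 0.34 SE. Fibroblast and matrix genes rose too, by a median of 0.30 with 22 of 24 higher (adjusted p = 2.88e-07; adjusted p = 0.424 with an estimated correlation), with the matrix proteoglycan Lum at 0.96 ± 0.23 SE. Without Lean 9 the macrophage and fibroblast medians were 0.13 and 0.16. With keratinocyte and fibroblast scores as covariates, chosen after the data were seen, MHC class II lay at 0.34, and macrophage markers lay at -0.01 and did not pass; with array weights the latter lay at 0.14.

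The cell cycle list rose with 29 of 31 members higher and a median of 0.37 (adjusted p = 1.04e-20; adjusted p = 0.133 with an estimated correlation). No member passed over all genes and 15 did adjusted over the list alone, among them Rrm2, a subunit of the enzyme that makes deoxyribonucleotides (0.63 ± 0.12 SE, adjusted p = 0.0888), and the transcription factor E2f1 (0.45 ± 0.11 SE). Cholesterol synthesis fell with 24 of 24 members lower and a median of -0.43 (adjusted p = 2.18e-16; adjusted p = 0.136 with an estimated correlation), 17 of them past the threshold adjusted over the list alone and none over all genes. Fdft1 and Hmgcs1, enzymes of the pathway, differed by -0.52 ± 0.13 SE and -0.56 ± 0.16 SE. Fatty acid synthesis genes fell with a median of -0.09 (adjusted p = 0.0193; adjusted p = 0.394 with an estimated correlation), with the acetyl-CoA synthetase Acss2 at -0.34 ± 0.09 SE. Their call was lost without DIO 1 or Lean 3 (medians -0.13 and -0.11), and without DIO 2, DIO 3 or Lean 5 they lay at -0.15, -0.05 and -0.06. They passed in 15 of 17 settings, with medians from -0.14 to -0.05, and not with the replicate block or without DIO 1 and 6. Differentiated keratinocyte markers moved with these lists and fell with 36 of 38 lower and a median of -0.44 (adjusted p = 8.83e-11; adjusted p = 0.299 with an estimated correlation). Lce3b and Lce3c, proteins of the cornified envelope, differed by -1.13 ± 0.37 SE and -1.16 ± 0.39 SE. Epithelial antimicrobial genes fell with a median of -0.42 (adjusted p = 0.0456; adjusted p = 0.628 with an estimated correlation), although the acute phase gene Saa2 was 1.56 ± 0.44 SE higher. They passed in 10 of 17 settings, were lost without DIO 1, 2, 6, 7 or 8, Lean 3, 4, 5, 6 or 10, or DIO-R 3, 5 or 6, and lay at -0.25 without Lean 10. With the keratinocyte and fibroblast covariates cholesterol synthesis lay at -0.21 and antimicrobial genes at -0.13, and with the replicate block differentiated keratinocyte markers lay at -0.24.

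The Bmal1 arm of the circadian clock fell in DIO with 7 of 7 members lower and a median of -0.42 (adjusted p = 6.01e-07), 5 of them past the threshold adjusted over the list alone, and it was the 1 list that held with an estimated correlation (adjusted p = 0.0264). Npas2, a partner of Bmal1, differed by -0.52 ± 0.14 SE. The opposing Per-Dbp arm rose with 10 of 13 members higher and a median of 0.28 (adjusted p = 2.73e-05; adjusted p = 0.155 with an estimated correlation). Glucocorticoid response genes fell with a median of -0.25 (adjusted p = 1.69e-05; adjusted p = 0.106 with an estimated correlation), with the metallothionein Mt1 at -0.38 ± 0.09 SE. Immediate early genes fell with a median of -0.20 (adjusted p = 0.0208; adjusted p = 0.36 with an estimated correlation), and the unfolded protein response rose by 0.06 (adjusted p = 0.0456; adjusted p = 0.628 with an estimated correlation) but lay at -0.02 within slide 2. Ribosomal protein genes fell with a median of -0.07 (adjusted p = 0.00887; adjusted p = 0.811 with an estimated correlation), a value that turned to 0.01 after quantile normalization and in the authors' value table. Of these calls, immediate early genes lost theirs without DIO 1, DIO 3 or Lean 5 (-0.14, -0.19 and -0.20), ribosomal genes without Lean 6 or DIO 6 (-0.05 and -0.04; -0.11 without DIO 3 and -0.10 without Lean 5), and the unfolded protein response without DIO 1, 3 or 6, Lean 3, 4 or 7, or DIO-R 6 (0.04 without DIO 3, 0.09 without DIO 2 or Lean 10). The Per-Dbp arm lay at 0.18 without Lean 4, 0.13 with normexp background and 0.47 with array weights. Immediate early, ribosomal and unfolded protein response genes passed in 13, 13 and 11 of 17 settings, with medians from -0.22 to -0.03, -0.10 to 0.05 and 0.03 to 0.17; ribosomal genes passed in 1 of these, with the keratinocyte and fibroblast covariates, in the opposite direction.

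The type II taste cell list, the receptors and transduction proteins of sweet, umami and bitter cells, fell with 13 of 13 members lower and a median of -0.29 (adjusted p = 0.0193; adjusted p = 0.628 with an estimated correlation). It lay at -0.43, -0.28 and 0.11 within slides 1, 2 and 3, lost its call without DIO 1 or DIO 6 (-0.08 and -0.16), and lay at 0.04 without both, an alternative chosen after the data were seen. It passed in 12 of 17 settings. DIO 1 and DIO 6 were picked as the DIO samples lowest in taste cell lists, so a smaller fall without them was likely beforehand. Neither lies on slide 3. Taste cell peptides and receptors fell with a median of -0.14 with 22 of 25 lower (adjusted p = 0.0121; adjusted p = 0.0843 with an estimated correlation), among them the adiponectin receptor Adipor1 at -0.21 ± 0.08 SE, did not pass without DIO 3 (-0.14), and lay at -0.09 with normexp background and in the authors' value table. No member of the panel passed. Cd36, a fatty acid receptor and transporter, differed by 0.03 ± 0.37 SE and Ffar4, the long-chain fatty acid receptor known as GPR120, by 0.12 ± 0.17 SE. The sweet and umami receptor subunit Tas1r3 differed by -0.32 ± 0.12 SE (adjusted p = 0.424), Tas1r2 by -0.58 ± 0.33 SE and Tas1r1 by -0.25 ± 0.18 SE. The transduction genes Gnat3, Plcb2, Trpm5 and Itpr3 differed by -0.35 ± 0.31, -0.06 ± 0.11, -0.36 ± 0.30 and -0.10 ± 0.11 SE. Pkd2l1, Entpd2, the leptin receptor Lepr and Glp1r differed by -0.12 ± 0.32, 0.01 ± 0.14, -0.06 ± 0.15 and -0.54 ± 0.25 SE. Gcg was not well above background on any array.

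In DIO against Lean 19 of the 37 lists were called, 9 up and 10 down, 16 of them kept their direction in every slide, and other splits of the same arrays called a median of 14 lists. With the slide as a block 17 of the 19 passed, all but the unfolded protein response and the neutrophil and mast cell list (both adjusted p = 0.0614). The count of called genes rested on single arrays: it was 37 without DIO 6, 22 without Lean 7, 8 without DIO-R 6, 3 without DIO 3, and 2 without DIO-R 2 or DIO-R 3.

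DIO-R against DIO was led by genes of fatty acid use, which fell. Pdk4, the kinase that shuts off pyruvate dehydrogenase (chromosome 6, positions 5433441 to 5433500), fell 6.82-fold (log2 difference -2.77 ± 0.44 SE, n = 8 and 8, adjusted p = 0.00644). Angptl4, a secreted inhibitor of lipoprotein lipase (chromosome 17, positions 33911880 to 33911939), fell 3.72-fold (-1.90 ± 0.17 SE, adjusted p = 4.1e-06), and Cpt1a, which carries fatty acids into mitochondria, fell 1.41-fold (-0.49 ± 0.07 SE, adjusted p = 0.00368). Scd2, a stearoyl-CoA desaturase, rose 1.67-fold (0.74 ± 0.11 SE, adjusted p = 0.00372). Of the clock, Dbp (chromosome 7, positions 52965461 to 52965520) rose 3.94-fold (1.98 ± 0.25 SE, adjusted p = 0.000711), and its relative Tef rose 1.71-fold (0.77 ± 0.13 SE, adjusted p = 0.0185). With the erythrocyte score as a covariate, chosen after the data were seen, Pdk4, Cpt1a, Scd2 and Tef differed by -2.01, -0.54, 0.79 and 0.80 and no longer passed. The differences of Cpt1a, Scd2 and Tef did not shrink. That score averaged 0.64 in DIO and -0.32 in DIO-R, which limits how far this fit can separate blood from the group. Without DIO 1 and 6, likewise chosen after the data were seen, the value for Pdk4, DIO-R against DIO, was -2.63 and that for Tef 0.69, and neither passed. Tef also lost its call with only the 2 groups compared, with muscle, adipocyte and gland scores as covariates (0.81), and without DIO 1, DIO 6, DIO-R 5 or DIO-R 10 (0.75, 0.72, 0.75 and 0.72).

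**Figure D1:**
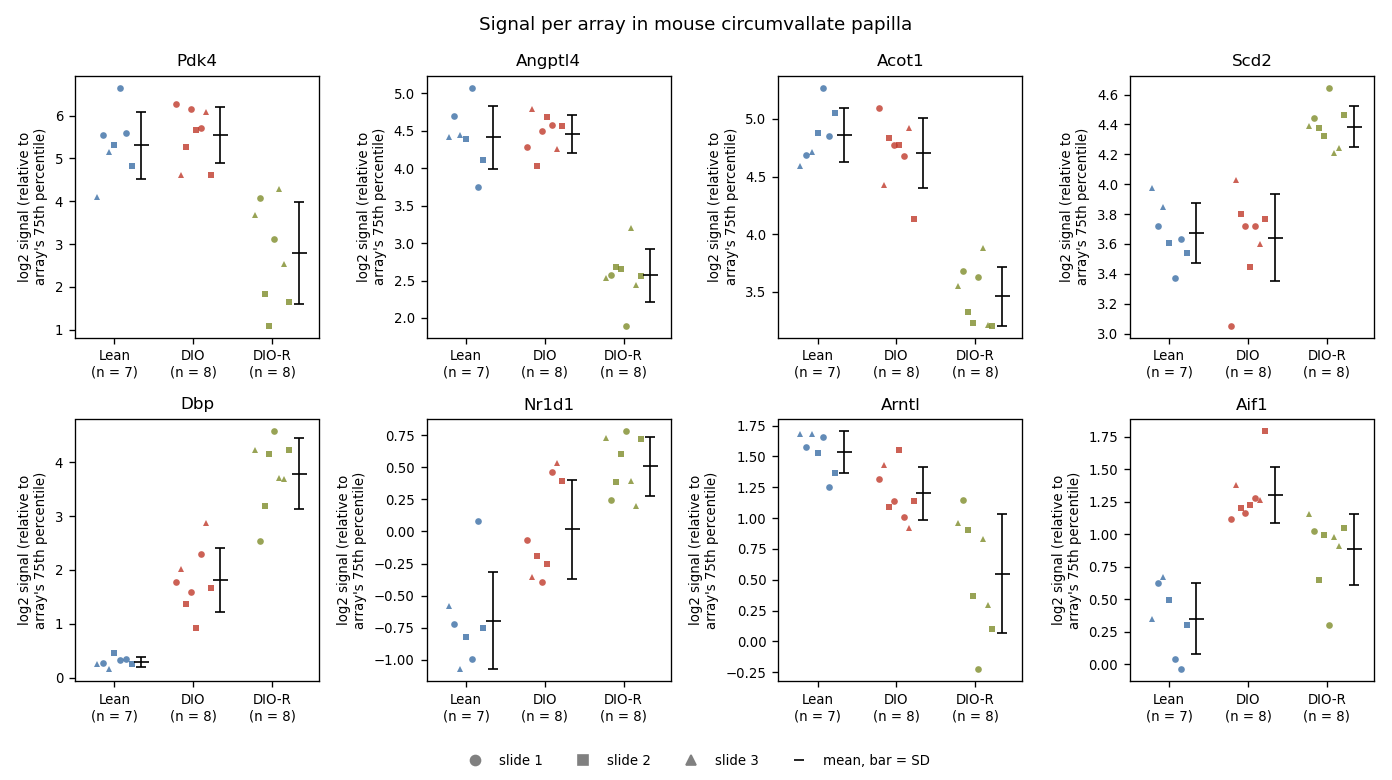
Log2 signal relative to the array's 75th percentile (vertical axis) of 8 genes in each Lean, DIO and DIO-R sample (horizontal axis), with points for samples, their shape for the slide, and bars for mean and SD. Angptl4 lay at 2.57 ± 0.36 (SD, n = 8) in DIO-R, below every DIO and Lean sample, and Dbp at 0.30 ± 0.10 in Lean, 1.81 ± 0.59 in DIO and 3.79 ± 0.66 in DIO-R.

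In all, 17 genes passed in DIO-R against DIO, 6 higher and 11 lower. The acyl-CoA thioesterases Acot1 and Acot5, which release fatty acids from coenzyme A, fell 2.37-fold and 2.42-fold (adjusted p = 5.36e-05 and 0.000711), and the other probe of Acot5 went the opposite way, so that with the mean of probes Acot5 lay at -0.59 and no longer passed. Eci3, an enoyl-CoA isomerase, fell 1.42-fold (adjusted p = 0.0389) and Impa2, an inositol monophosphatase, 1.61-fold (adjusted p = 0.000711). The transcription factor Klf11 fell 1.53-fold (adjusted p = 0.00486) and the membrane protein Tmem82 2.85-fold (adjusted p = 0.0058). With normexp background they differed by -0.39 and -0.71, and Tmem82 no longer passed, as it did not without DIO 1 and 6. Terb1, a meiotic telomere protein, was well above background in 5 of 8 DIO and 0 of 8 DIO-R samples and fell at least 1.66-fold (adjusted p = 0.0185). That bound does not hold with normexp background, where Terb1 differed by -0.18, and it passed in 8 of 15 settings, not with normexp or with trend and robust eBayes, and had no value in the authors' value table. Bhlhe40, a clock-controlled repressor, rose 1.69-fold and Bdh1, an enzyme of ketone body metabolism, 1.49-fold (both adjusted p = 0.0389). The zinc finger factor Hivep2 rose 1.34-fold (adjusted p = 0.0328). All 16 of the called genes named lay beyond the DIO mean in 8 of 8 DIO-R samples and kept their direction within each of the 3 slides. Angptl4 differed by -2.22, -1.80 and -1.80, Pdk4 by -2.45, -3.66 and -1.86, and Dbp by 1.67, 2.53 and 1.44 within slides 1, 2 and 3. With the slide as a block these were -1.91, -2.70 and 1.95 (adjusted p = 2e-05, 0.00135 and 0.00135), and 13 of the 16 passed, all but Bdh1, Bhlhe40 and Hivep2. With 1 of the 23 arrays left out at a time Bdh1, Eci3, Bhlhe40 and Hivep2 passed in 7, 7, 9 and 11 fits and Terb1 in 20, all but those without DIO 1, DIO 6 or DIO 8; Bhlhe40 and Eci3 also lost their calls with only the 2 groups compared. With the erythrocyte covariate Acot5, Impa2, Klf11, Tmem82, Eci3, Bhlhe40, Bdh1 and Hivep2 differed by -1.12, -0.56, -0.56, -1.36, -0.36, 0.73, 0.49 and 0.28 and, like Terb1, no longer passed.

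The list of PPAR targets and fatty acid oxidation fell with 31 of 37 members lower and a median of -0.34 (adjusted p = 2.6e-22), and held with an estimated correlation (adjusted p = 0.0267). Over all genes 4 of its members passed, Pdk4, Angptl4, Acot1 and Cpt1a, and 19 fell when adjusted over the list alone. It lay at -0.30, -0.46 and -0.16 within slides 1, 2 and 3 and at -0.32 with the slide as a block. Skeletal muscle markers moved with it, at a median of -0.56 with 26 of 28 lower (adjusted p = 1.78e-06; adjusted p = 0.472 with an estimated correlation), and so did adipocyte markers at -0.51 with 14 of 16 lower (adjusted p = 0.000871; adjusted p = 0.434 with an estimated correlation). Both lay on the other side within slide 3, at 0.25 and 0.13. The muscle gene Pvalb differed by -1.19 ± 0.40 SE, and Pparg, the PPAR of fat cells, by 0.26 ± 0.06 SE. Respiratory chain genes fell with a median of -0.09 (adjusted p = 0.000677; adjusted p = 0.58 with an estimated correlation) and lay at 0.08 within slide 3, at -0.06 without DIO-R 5 or DIO-R 10 and at -0.14 without DIO-R 7. Muscle markers lay at -0.33 without DIO-R 5. With the erythrocyte covariate muscle and adipocyte markers lay at 0.04 and -0.34 and did not pass, and respiratory chain genes turned to 0.09. With muscle, adipocyte and gland scores as covariates, chosen after the data were seen, the PPAR list lay at -0.20 and respiratory chain genes at 0.09, and adipocyte markers lay at -0.23 with normexp background and -0.33 without DIO 1 and 6.

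Genes of lipid synthesis rose in DIO-R. Cholesterol synthesis rose with 23 of 24 members higher and a median of 0.40 (adjusted p = 5.14e-15; adjusted p = 0.198 with an estimated correlation), 16 of them past the threshold adjusted over the list alone and none over all genes. Mvd differed by 0.48 ± 0.13 SE. Fatty acid synthesis rose by a median of 0.19 with 18 of 23 higher (adjusted p = 1.83e-05; adjusted p = 0.134 with an estimated correlation), and Scd2 was its 1 member past the threshold over all genes. Epithelial markers rose beside them: differentiated keratinocyte markers with 38 of 38 higher and a median of 0.38 (adjusted p = 5.37e-08; adjusted p = 0.452 with an estimated correlation), and basal keratinocyte markers by 0.19 (adjusted p = 0.000137; adjusted p = 0.452 with an estimated correlation). Tgm1, which cross-links the cornified envelope, differed by 0.61 ± 0.19 SE. Epithelial antimicrobial genes rose by a median of 0.35 (adjusted p = 0.0159; adjusted p = 0.494 with an estimated correlation), a call lost without DIO 1, DIO 2 or DIO-R 4 (0.32, 0.22 and 0.26). Antimicrobial genes passed in 12 of 17 settings, with medians from -0.10 to 0.39. Without DIO 6 basal keratinocyte markers lay at 0.11, and without DIO 1 and 6 they lay at 0.06 and did not pass. With keratinocyte and fibroblast scores as covariates, chosen after the data were seen, cholesterol synthesis, fatty acid synthesis and basal keratinocyte genes lay at 0.23, 0.11 and 0.12, and with muscle, adipocyte and gland scores fatty acid synthesis lay at 0.11.

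The Per-Dbp arm of the clock rose with 13 of 13 members higher and a median of 0.57 (adjusted p = 2.1e-16), and held with an estimated correlation (adjusted p = 0.0137). Dbp and Tef passed over all genes and 10 members did adjusted over the list alone; Per2, a core clock repressor, differed by 1.16 ± 0.23 SE (adjusted p = 0.0547). Within slides 1, 2 and 3 the list lay at 0.51, 0.70 and 0.44, and at 0.58 with the slide as a block. The Bmal1 arm was not called (adjusted p = 0.187), with a median of 0.07, a mean of -0.16 and a test pointing down. Immediate early genes rose by a median of 0.28 (adjusted p = 9.07e-06; adjusted p = 0.0809 with an estimated correlation), with the growth-induced transcription factor Egr1 at 1.18 ± 0.28 SE. Heat shock genes rose by 0.12 (adjusted p = 0.00177; adjusted p = 0.463 with an estimated correlation), with the chaperone Hspa1a at 0.69 ± 0.15 SE, and lay at 0.05 without DIO 6, 0.08 without DIO-R 8 and 0.20 without DIO 3. They did not pass without DIO 1 and 6 (0.04), and lay at 0.07 in the authors' value table, 0.08 with the erythrocyte covariate and 0.03 with the keratinocyte and fibroblast covariates, where immediate early genes lay at 0.18.

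Immune groups fell in DIO-R against DIO. MHC class II fell with 11 of 11 lower and a median of -0.47 (adjusted p = 1.03e-06; adjusted p = 0.263 with an estimated correlation), macrophage and dendritic cell markers with a median of -0.28 (adjusted p = 5.97e-05; adjusted p = 0.434 with an estimated correlation) and interferon response with a median of -0.32 (adjusted p = 0.000224; adjusted p = 0.513 with an estimated correlation). Interferon response lost its call without DIO 3, at a median of -0.04 (adjusted p = 0.201), and lay at -0.18 and -0.17 without DIO-R 6 and DIO-R 4, while macrophage markers lay at -0.18 without DIO-R 6. The MHC class II chaperone Cd74 differed by -0.51 ± 0.18 SE and Aif1 by -0.42 ± 0.13 SE (adjusted p = 0.409). Erythrocyte markers moved with these groups and fell with 8 of 8 lower and a median of -1.05 (adjusted p = 1.06e-09; adjusted p = 0.0809 with an estimated correlation), with Alas2, the first enzyme of haem synthesis in red cells, at -0.77 ± 0.22 SE. Fibroblast genes fell with a median of -0.19 (adjusted p = 0.00686; adjusted p = 0.585 with an estimated correlation) and endothelial and smooth muscle markers with a median of -0.21 (adjusted p = 0.0026; adjusted p = 0.463 with an estimated correlation). Cell cycle genes fell with a median of -0.17 (adjusted p = 0.00123; adjusted p = 0.543 with an estimated correlation), while cytokines and NF-kB targets rose by 0.08 (adjusted p = 0.0224; adjusted p = 0.497 with an estimated correlation). The fibroblast call was lost without DIO-R 6, DIO 6 or DIO 2 (-0.10, -0.13 and -0.13), the cell cycle call without DIO 3 (-0.11), and the cytokine call without DIO 1, 6 or 7 or DIO-R 4 or 5 (0.06, 0.06, 0.07, 0.06 and 0.06). Without DIO 3 the fibroblast, endothelial and cytokine medians were -0.32, -0.33 and 0.12, and cytokines lay at 0.16 without DIO 10 and 0.13 without DIO-R 8. Endothelial genes passed in 13 of 17 settings, not without DIO 1 and 6 (-0.14) or with the muscle, keratinocyte or erythrocyte sets of covariates (-0.19, -0.03 and -0.04). Cytokines passed in 11 of 17, with medians from 0.02 to 0.12, and fibroblast genes in all but that with the erythrocyte covariate (-0.05; -0.37 with the muscle set). With the keratinocyte set macrophage and cell cycle genes lay at -0.14 and -0.27. Interferon response lay at -0.18 with normexp background, -0.20 in the authors' value table and -0.51 without DIO 1 and 6.

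All 4 lists of taste cell classes rose in DIO-R against DIO by the list test. The type II, type I, type III and bitter receptor lists had medians of 0.28, 0.30, 0.30 and 0.26 (adjusted p = 0.00237, 0.0097, 0.0105 and 0.0103). With an estimated correlation their adjusted p-values were 0.463, 0.452, 0.463 and 0.497. Of 100 splits of the same arrays, the real one included, 35, 18, 46 and 46 gave these lists a p as small. Taste bud renewal rose by 0.21 (adjusted p = 0.0013; adjusted p = 0.463 with an estimated correlation), with the Notch target Hes1 at 0.36 ± 0.11 SE. Within slide 3 all 5 lay below 0, at -0.14, -0.22, -0.08, -0.16 and -0.12, and without DIO samples 1 and 6 none passed, at -0.09, 0.01, 0.05, 0.02 and 0.00. DIO 1 and 6 were picked as the DIO samples lowest in taste cell lists, so a smaller rise without them was likely beforehand. Neither lies on slide 3, so its values are no separate check. With normexp background the type II, type III and bitter lists lay at 0.18, 0.15 and 0.05. The 5 lists passed in 14, 14, 13, 10 and 14 of 17 settings, and not with muscle, adipocyte and gland scores as covariates (0.05, 0.13, 0.08, 0.10 and 0.04). Without DIO 1 alone all 5 lost their call, at 0.10, 0.17, 0.09, 0.15 and 0.08, and without DIO 6 the type II list lay at 0.18 and the bitter list lost its call at 0.16. No panel gene passed: Cd36 differed by -0.84 ± 0.36 SE (adjusted p = 0.492), Ffar4 by -0.14 ± 0.17 SE, Tas1r3 by 0.28 ± 0.12 SE, Itpr3 by 0.27 ± 0.10 SE and Glp1r by 0.51 ± 0.24 SE. Von Ebner gland and salivary markers fell with 21 of 21 lower and a median of -0.37 (adjusted p = 0.00767; adjusted p = 0.566 with an estimated correlation), and lay at 0.05 without DIO samples 1 and 6. Their call was lost without DIO 1, DIO 6 or DIO-R 5 (-0.23, -0.13 and -0.20), and they lay at -0.56 without DIO 10 and passed in 12 of 16 settings. The carbonic anhydrase of gland secretion, Car6, differed by -1.66 ± 1.06 SE.

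In this comparison 26 lists were called, 14 up and 12 down, and 17 of them kept their direction in every slide, and other splits of the same arrays called a median of 16 lists. The count of called genes was 11 without each of DIO 1, DIO 6, DIO 8, DIO-R 5 and DIO-R 10, 10 without DIO 1 and 6 together, of which 8 were among the 17, and 3, those of Acot1, Angptl4 and Dbp, with the erythrocyte score as a covariate, alternatives of which the last 2 were chosen after the data were seen. Without DIO 1 and 6 the calls lost included those of Pdk4, Tef, Tmem82, Terb1, Eci3, Bhlhe40, Bdh1 and Hivep2.

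DIO-R against Lean was led by clock genes. Dbp rose 11.2-fold (log2 difference 3.49 ± 0.26 SE, n = 8 and 7, adjusted p = 1.74e-07). The clock repressors Per2, Nr1d1 and Nr1d2 rose 2.71-fold, 2.30-fold and 2.28-fold (adjusted p = 0.00625, 0.00165 and 0.000243), and Arntl, which encodes the clock activator Bmal1, fell 1.98-fold (-0.99 ± 0.17 SE, adjusted p = 0.00768). Pdk4 fell 5.77-fold (-2.53 ± 0.45 SE, adjusted p = 0.0155), Angptl4 3.59-fold (-1.85 ± 0.17 SE, adjusted p = 6.49e-06), and Acot1 2.64-fold (-1.40 ± 0.14 SE, adjusted p = 7.57e-06). Of fat synthesis, Srebf1, the transcription factor of lipogenic enzymes, rose 1.59-fold (adjusted p = 0.00602) and Scd2 1.64-fold (adjusted p = 0.00602). With only the 2 groups compared, which leaves the differences as they are, Per2, Arntl and Pdk4 no longer passed. With muscle, adipocyte and gland scores as covariates, chosen after the data were seen, Per2, Arntl and Scd2 differed by 1.29, -1.04 and 0.49 and did not pass. Per2 lay at 0.87 with normexp background and passed there.

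**Figure D2:**
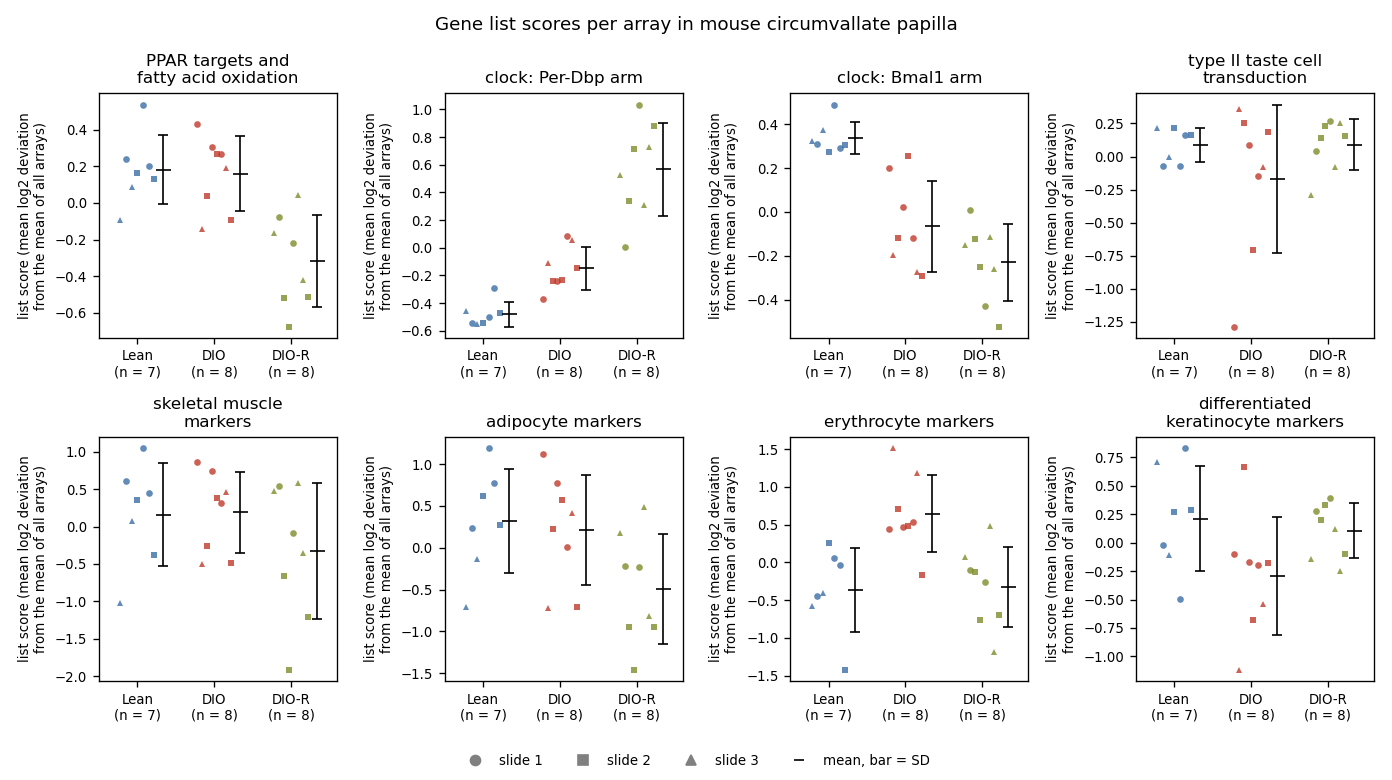
List score (vertical axis), the mean over a list's genes of the log2 deviation from each gene's mean over all arrays, in each Lean, DIO and DIO-R sample (horizontal axis) for 8 lists, with points for samples, their shape for the slide, and bars for mean and SD. The type II taste score ranged from -1.29 to 0.36 over the 8 DIO samples, and the erythrocyte score averaged 0.64 in DIO, -0.37 in Lean and -0.32 in DIO-R.

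In all, 36 genes passed in DIO-R against Lean, 15 higher and 21 lower. Nfil3, a repressor of the genes that Dbp activates, fell 2.32-fold (adjusted p = 0.00515), Tef rose 2.16-fold (adjusted p = 0.000243) and Bhlhe40 1.66-fold (adjusted p = 0.0417). Acot5 and Acot2 fell 3.03-fold and 2.00-fold (adjusted p = 3.44e-05 and 0.0338), Cpt1a 1.45-fold (adjusted p = 0.00126) and Tmem82 2.55-fold (adjusted p = 0.0156). The helix-loop-helix factor Tcf23 fell 3.72-fold (adjusted p = 0.00625) and Camkv, a calmodulin-binding pseudokinase, rose 2.47-fold (adjusted p = 0.00625). Of chemokines, Ccl3 rose 2.00-fold (adjusted p = 0.0417) and Cxcl5, an attractant of neutrophils, fell 2.16-fold (adjusted p = 0.0338). With 1 of the 23 arrays left out at a time Ccl3 passed in 9 fits, those without DIO 3, 5, 6, 8 or 10 or DIO-R 3, 5, 7 or 8. Cxcl5 lost its call without Lean 4, 5, 6, 7, 9 or 10 or DIO-R 2, 5, 6, 8 or 10 (12 passed), Acot2 without Lean 4, 5, 6 or 9 or DIO-R 4, 5, 6, 8 or 10 (14 passed), and Bhlhe40 passed in 8. With only the 2 groups compared Acot2, Ccl3, Tcf23 and Tmem82 no longer passed. With the muscle, adipocyte and gland covariates Nfil3, Bhlhe40, Acot2, Tmem82, Tcf23, Camkv, Ccl3 and Cxcl5 differed by -1.06, 0.54, -0.69, -0.94, -1.89, 1.20, 0.92 and -1.06 and did not pass. With normexp background Tmem82 and Ccl3 lay at -0.66 and 0.31 and did not pass, and Tcf23 lay at -1.02 and passed. Acot2 did not pass after quantile normalization, nor Acot2 and Tmem82 in the authors' value table (-0.77 and -0.80). With the mean of probes Acot5 lay at -0.88 and passed. All 21 of the called genes named lay beyond the Lean mean in 8 of 8 DIO-R samples and kept their direction within each of the 3 slides. Dbp differed by 3.24, 3.49 and 3.67, Arntl by -1.04, -0.99 and -0.98, and Pdk4 by -2.33, -3.54 and -1.12 within slides 1, 2 and 3. With the slide as a block Dbp and Pdk4 differed by 3.48 and -2.36 (adjusted p = 9.74e-07 and 0.00892), and Bhlhe40 was the 1 of the 21 that no longer passed.

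The Per-Dbp arm rose with 13 of 13 members higher and a median of 1.11 (adjusted p = 4.39e-26), and the Bmal1 arm fell with 7 of 7 lower and a median of -0.37 (adjusted p = 7.27e-09). Both held with an estimated correlation (adjusted p = 0.000925 and 0.00251). In the Per-Dbp arm 7 members passed over all genes and 10 adjusted over the list alone, and in the Bmal1 arm 2 and 5. Within slides 1, 2 and 3 the Per-Dbp arm lay at 0.95, 1.30 and 1.02 and the Bmal1 arm at -0.33, -0.58 and -0.39. The PPAR list fell with 35 of 37 lower and a median of -0.29 (adjusted p = 3.6e-20), and held with an estimated correlation (adjusted p = 0.0289). Of its members 7 passed over all genes and 17 adjusted over the list alone, and it lay at -0.25, -0.46 and -0.11 within slides. Beside it, skeletal muscle and adipocyte markers fell with medians of -0.52 and -0.56 (both adjusted p = 0.000136; adjusted p = 0.695 and 0.415 with an estimated correlation), and lay at 0.74 and 0.31 within slide 3. Muscle markers lay at -0.34 without Lean 7 and lost their call without DIO-R 5 (-0.27). With muscle, adipocyte and gland scores as covariates the PPAR list lay at -0.09 and passed, and with normexp background the Per-Dbp arm and adipocyte markers lay at 0.63 and -0.30, the latter at -0.34 in the authors' value table. Glucocorticoid response genes, which share Angptl4 with the PPAR list, fell with a median of -0.09 (adjusted p = 0.000136; adjusted p = 0.224 with an estimated correlation).

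In DIO-R against Lean cell cycle genes rose by a median of 0.15 with 26 of 31 higher (adjusted p = 3.05e-08; adjusted p = 0.549 with an estimated correlation), with Ccne1, a cyclin of entry into S phase, at 0.78 ± 0.18 SE, and lay at 0.09 without Lean 10 and 0.24 without Lean 3. Interferon response rose by 0.36 (adjusted p = 8.89e-08; adjusted p = 0.549 with an estimated correlation), with Gbp3 at 0.83 ± 0.29 SE. Heat shock genes rose by 0.17 (adjusted p = 6.56e-07; adjusted p = 0.377 with an estimated correlation), with Hsph1 at 0.70 ± 0.19 SE. The immediate early list rose by 0.13 (adjusted p = 0.0374; adjusted p = 0.549 with an estimated correlation), with Fos at 1.21 ± 0.33 SE, lay at -0.08 within slide 3, and did not pass without Lean 3, 7 or 9 or DIO-R 3, 4, 5 or 10 (medians from 0.10 to 0.18). Cytokines and NF-kB targets rose by 0.11 and the unfolded protein response by 0.15 (adjusted p = 0.00367 and 0.00502; both adjusted p = 0.549 with an estimated correlation). Basal keratinocyte markers rose by 0.14 and taste bud renewal by 0.11 (adjusted p = 0.00159 and 0.0123; adjusted p = 0.576 and 0.683 with an estimated correlation), at -0.01 and -0.05 within slide 3. Fibroblast genes rose by 0.14 and respiratory chain genes fell with a median of -0.09 (adjusted p = 0.0311 and 0.0375; adjusted p = 0.841 and 0.877 with an estimated correlation), at -0.01 within slide 1 and 0.20 within slide 3. The fibroblast call was lost without Lean 9 (0.02), Lean 10 (0.07) or DIO-R 2, 3, 4 or 7 (0.07 without DIO-R 2; 0.23 without DIO-R 6), and the respiratory chain call without Lean 4, 6, 7 or 9 or DIO-R 4, 5, 8 or 10 (-0.04 without Lean 7, -0.05 without DIO-R 5 or 10, -0.06 without DIO-R 4). Gland markers fell with 21 of 21 lower and a median of -0.97 (adjusted p = 1.13e-05; adjusted p = 0.549 with an estimated correlation), at 0.03 within slide 3 and -0.47 without DIO-R 5, with Car6 at -3.48 ± 1.09 SE. With muscle, adipocyte and gland scores as covariates cell cycle genes lay at 0.03 and passed, while cytokines, basal keratinocyte markers and taste bud renewal lay at -0.03, 0.07 and -0.09 and did not. Immediate early and respiratory chain genes passed in 13 and 9 of 17 settings, with medians from 0.10 to 0.22 and -0.10 to 0.10, the last of these in the opposite direction and with the covariates just named, and fibroblast genes in 11 of 16, from -0.19 to 0.16. Cytokines lay at 0.05 with normexp background and 0.07 with the mean of probes, and taste bud renewal did not pass with the replicate block.

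The lists of taste cell classes and fat sensing were not called in DIO-R against Lean: the type II, type III, type I and bitter lists had adjusted p-values of 0.591, 0.39, 0.518 and 0.111. No panel gene passed, with Cd36 at -0.81 ± 0.37 SE (adjusted p = 0.523), Ffar4 at -0.02 ± 0.17 SE, Gnat3 at 0.05 ± 0.31 SE and Lepr at -0.11 ± 0.15 SE. Fatty acid sensing was not called in DIO against Lean, DIO-R against DIO or DIO-R against Lean (adjusted p = 0.919, 0.303 and 0.343), nor were lymphocyte markers (0.176, 0.394 and 0.583), glucose uptake and glycolysis (0.289, 0.204 and 0.789), nerve and Schwann cell markers (0.606, 0.204 and 0.496), or oxidative stress and xenobiotic response (0.606, 0.935 and 0.705). Cholesterol synthesis, at a median of -0.04, and erythrocyte markers, at 0.10, were not called in DIO-R against Lean (adjusted p = 0.789 and 0.71). Median, mean and test had the same sign for every called list; among lists not called in a comparison they differed for Bmal1 arm, lymphocyte, nerve, oxidative stress, PPAR, glucocorticoid, type II, antimicrobial and glycolysis genes. In this comparison 17 lists were called, 10 up and 7 down, 9 of them kept their direction in every slide, and other splits of the same arrays called a median of 12 lists. With the slide as a block 15 of the 17 passed, all but respiratory chain and fibroblast genes (adjusted p = 0.591 and 0.0658). The gene count was 65 without Lean 3, 58 without DIO 1 and 6, 127 with keratinocyte and fibroblast scores as covariates and 20 with muscle, adipocyte and gland scores, of which 13 were among the 36, the last 3 being alternatives chosen after the data were seen.

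The comparisons share arrays. Across genes, which are not independent replicates, the differences of DIO from Lean and of DIO-R from Lean correlated at 0.462, against a mean of 0.531 in simulated unchanged groups that shared the Lean arrays and 0.0351 with the Lean arrays split. The covariance was 0.033 against a simulated 0.0341, a difference of -0.00108. Within slides 1, 2 and 3 the correlation was 0.0961, 0.677 and 0.645. The 1 gene called in DIO against Lean, Aif1, was not called in the opposite direction in DIO-R against DIO, where 2745 genes had an unadjusted p under 0.05. Of the genes called in DIO-R against DIO, 14 were called in the same direction in DIO-R against Lean, among them Angptl4, Pdk4, Acot1, Cpt1a, Dbp, Tef and Scd2; simulated unchanged groups gave 0, independent lists 0.0114, and splits of the DIO-R arrays a mean of 4.06. The DIO-R arrays stand in both comparisons, so part of that overlap may come from them. The simulated groups hold no true change, so their 0 cannot show how large that part is.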

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

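Chosen only after the result was seen were the tests with blood, muscle, adipocyte, keratinocyte and fibroblast scores as covariates. So were the test of macrophage markers on Aif1, the splits counted list by list, and the look at the split with 384 genes. The Aif1 pattern was restated after its first tests.

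Single samples far from the rest of their group were searched with Dixon's ratio, the gap to the nearest sample divided by the group's range, among the named genes and the list scores. It exceeded the 95% critical value in 19 of 336 groups of gene values and in 9 of 111 groups of list scores, where chance alone gives about 1 in 20, that is 16.8 and 5.55. DIO-R 6 and DIO 3 had 4 of the gene values each, and DIO-R 6 had 3 of the list scores.

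DIO-R 6 was the lowest of its group in MHC class II genes, with a ratio of 0.593 for H2-Ab1, 0.585 for H2-Eb1 and 0.566 for the MHC class II score. It was also the lowest in the macrophage and dendritic cell score (0.725), the nerve and Schwann cell score (0.606) and Col5a2 (0.607), and the highest in Mvd (0.598). DIO 3 was the highest in Pdia6 (0.634), Bst2 (0.599) and the epithelial antimicrobial score (0.632), and the lowest in Slamf9 (0.536) and Cldn5 (0.70). DIO 1 was the lowest in Pkd2l1 (0.613), Syt1 (0.629) and the type III taste cell score (0.655). DIO 10 was the highest in Aif1 (0.618), Tlr12 (0.57) and the lymphocyte score (0.541), and Aif1 still differed by 0.88 without it (adjusted p = 0.0146). Lean 7 was the highest in Acot2 (0.783) and the lowest in Oxtr (0.67) and the epithelial antimicrobial score (0.707). Lean 9 was the highest in Nr1d1 (0.576) and the Per-Dbp score (0.638). Lean 3 was the lowest in Cd36 (0.596). DIO-R 5 was the highest in Ccl3 (0.563) and the lowest in the gland score (0.633), DIO-R 8 the highest in Ifi27l2a (0.57), and DIO 6 the highest in Nfil3 (0.617).

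Other splits of the arrays into groups of the same sizes, 100 in each comparison with the real one included, were tested with the same limma fit. In DIO against Lean 3 of the 100 called at least 1 gene, the real count, fewer than the 5 set beforehand for chance. The 2 other splits with a call had 109 and 384 genes, far more than the real 1. Chance is therefore not excluded for a count this small. The split with 384 put 6 DIO and 2 Lean samples against 2 DIO and 5 Lean samples and did not follow the slides, and so high a count points to a structure among the samples. Its sides differed by -0.77 in the differentiated keratinocyte score, -0.62 in the antimicrobial score, 0.59 in the erythrocyte score and 0.57 in the fibroblast score. In DIO-R against DIO and in DIO-R against Lean 1 of the 100 splits, the real one, reached 17 and 36 genes, where the highest other split called 1 gene in each. Chance is unlikely for these counts, though 100 splits cannot exclude it.

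For called lists chance cannot be excluded in DIO against Lean, where 18 of the 100 splits called at least 19 lists and the highest other called 23. Nor can it be excluded in DIO-R against Lean, where 12 of the 100 called at least 17 and the highest other called 20. In DIO-R against DIO 1 of the 100, the real one, called 26, fewer than the 5 set beforehand for chance. The highest other split called 25, so the margin is narrow and chance is unlikely for the count rather than excluded. List by list, fewer than 5 of 100 splits gave a p as small for 7 of 19, 5 of 26 and 6 of 17 lists. These were MHC class II, the Bmal1 arm, the Per-Dbp arm, cholesterol synthesis, erythrocyte, cell cycle, and neutrophil and mast cell genes in DIO against Lean. In DIO-R against DIO they were PPAR targets, cholesterol synthesis, the Per-Dbp arm, erythrocyte and fatty acid synthesis genes. In DIO-R against Lean they were PPAR targets, both clock arms, taste bud renewal, heat shock and glucocorticoid genes. For every other called list at least 5 splits did so, up to 62 for respiratory chain genes in DIO-R against Lean.

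PPAR target and fatty acid oxidation genes were lower in DIO-R than in DIO, by -0.48 ± 0.11 SE in the list score. Skeletal muscle and adipocytes carry many of these transcripts, and less of both tissues in the DIO-R samples may explain part of the difference. With muscle and adipocyte scores as covariates, after removal of shared genes, it was -0.29 ± 0.04 SE, so that this is argued against as the whole cause and stays open as a part. With the slide as a block it was -0.45 ± 0.09 SE, and -0.48, -0.64 and -0.21 within the slides, which argues against the slide. A lower use of fatty acids under restriction, which the design names, stays open and untested. The hour of sampling, which the labels do not give, cannot be told apart from the group for these genes.

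In DIO-R against Lean the Per-Dbp arm of the clock was higher and the Bmal1 arm lower, with a difference between the arm scores of 1.61 ± 0.19 SE. It was 1.51 ± 0.21 SE with muscle and adipocyte scores as covariates and 1.60 ± 0.20 SE with the slide as a block, and 1.54, 1.74 and 1.55 within the slides. These values argue against less muscle and fat tissue, and against the slide, as the whole cause. Gland, keratinocyte and fibroblast content was not part of this test. The hour of sampling cannot be told apart from the group, since the labels give no hour, and a shift of the clock by restricted or timed feeding stays open too. The arm difference averaged -0.82 ± 0.13 (SD, n = 7) in Lean, -0.08 ± 0.33 (SD, n = 8) in DIO and 0.80 ± 0.50 (SD, n = 8) in DIO-R.

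Aif1 was higher in DIO than in Lean by 0.95 ± 0.13 SE. With the erythrocyte score as a covariate the difference was 1.03 ± 0.17 SE, which argues against blood as the whole cause. The adjusted p rose to 0.0593 because the SE grew while the difference did not fall. That score itself averaged 0.64 in DIO and -0.37 in Lean, which limits how far this fit can separate blood from the group. Over all other alternatives the adjusted p lay between 0.00118 and 1, the highest of these within single slides. With keratinocyte and fibroblast scores as covariates the difference was 0.86 ± 0.12 SE (adjusted p = 0.0141), which argues against a shift from epithelium to connective tissue as the whole cause. More macrophages carrying all their markers would need the other markers to rise alike. Their median was 0.22 ± 0.06 SE, an SE taken over the markers and not over the samples. They ran from Itgax at 0.65, Cd207 at 0.56, Ptprc at 0.50 and Adgre1 at 0.48 to Lyz2 at -0.01 and Cd163 at -0.48. C1qa and Cd68 lay between, at 0.28 and 0.10. Aif1 was picked as the gene of smallest p among all genes, so a lower median of the others was likely beforehand and cannot decide the question. More macrophages and a change in their state or kind with the diet both stay open, as untested hypotheses.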

How the results depend on the processing

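Chosen after seeing the data were the 3 sets of covariates and the fit without DIO 1 and 6; the other alternatives were chosen before the data were examined.

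In the alternatives with 1 value per gene, no called gene that the text names changed direction; with every probe on its own, the other probe of Acot5 went the opposite way in DIO-R against DIO. The count of genes in DIO against Lean, 1, became 3 with normexp background, 9 in the authors' value table, 3 with the slide as a block, 61 with array weights and 3 with trend and robust eBayes. In DIO-R against DIO 17 genes became 27 after quantile normalization, 26 in the authors' value table and 38 with array weights, and in DIO-R against Lean 36 became 110 with array weights. With the muscle, adipocyte and gland covariates the counts in DIO against Lean and DIO-R against Lean were 10 and 20 (13 of the 20 among the 36), with the keratinocyte and fibroblast covariates 4 and 127, and with the erythrocyte covariate DIO-R against DIO had 3, those of Acot1, Angptl4 and Dbp. Without DIO 1 and 6 the counts were 27, 10 (8 of them among the 17) and 58, and 1 gene was called in opposite directions in DIO against Lean and DIO-R against DIO. The cause was not tested. Filters on dim probes, the mean of probes, every probe, outlier spots kept and only the groups compared left each count within 1.5 times, but not each call. With only the groups compared 17 of the 36 genes in DIO-R against Lean were lost, among them Pdk4, Per2, Arntl, Acot2, Ccl3, Tcf23 and Tmem82, and 4 of the 17 in DIO-R against DIO, among them Tef, Bhlhe40 and Eci3.

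Within slides 1, 2 and 3 limma called 0 genes in each comparison, with fewer samples in each fit. The counts at an unadjusted p under 0.05, for genes called, DIO against Lean, were 606, 1354 and 2086; for genes called, DIO-R against DIO, they were 1860, 1391 and 935, and for genes called, DIO-R against Lean, 1482, 2510 and 1036. The correlation across genes of DIO minus Lean with DIO-R minus Lean was 0.0961, 0.677 and 0.645. The replicate block called 0, 4 and 9 genes (1349, 2169 and 2534 at an unadjusted p under 0.05), but replicate numbers do not pair the samples: of 18 pairs with the same number 4 correlated above 0.1, with a median of -0.0303, and 4 of 21 arrays correlated best with their own number.

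With 1 array left out at a time the gene counts ran from 1 to 37 in DIO against Lean, 11 to 24 in DIO-R against DIO and 26 to 65 in DIO-R against Lean. List counts ran from 14 to 21, 18 to 27 and 14 to 21, the correlation across genes of DIO minus Lean with DIO-R minus Lean from 0.37 to 0.546, and opposite calls stayed at 0. The count in DIO against Lean was 37 without DIO 6, 22 without Lean 7, 8 without DIO-R 6, 3 without DIO 3 and 2 without DIO-R 2 or 3. The count in DIO-R against DIO was 11 without DIO 1, DIO 6, DIO 8, DIO-R 5 or DIO-R 10, and in DIO-R against Lean 65 without Lean 3. Aif1, 10 of the 17 genes and 26 of the 36 were called whichever array was left out.

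List counts of 19, 26 and 17 became 1, 2 and 3 with an estimated correlation and 6, 6 and 4 with fry, which tests whether a list moves at all. Within slide 3, 13 lists were called in DIO-R against DIO, as against 17 with muscle, adipocyte and gland covariates and 17 without DIO 1 and 6, and in DIO-R against Lean 11 with the former covariates. A list used as a covariate has no value there, and every probe on its own gives no list test.

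The median for ribosomal proteins, DIO against Lean, turned to 0.0089 after quantile normalization, 0.00675 in the authors' value table, 0.0028 within slide 1 and 0.047 with keratinocyte and fibroblast covariates. With these covariates macrophage markers in DIO against Lean turned to -0.011 and antimicrobial genes in DIO-R against DIO to -0.098. With the erythrocyte covariate muscle and respiratory chain genes in DIO-R against DIO turned to 0.0432 and 0.0901. With muscle, adipocyte and gland covariates respiratory chain genes turned to 0.088 in DIO-R against DIO and 0.0997 in DIO-R against Lean, and in the latter cytokines turned to -0.026, taste bud renewal to -0.088 and fibroblast genes to -0.19. Fibroblast genes in DIO-R against Lean turned to -0.013 within slide 1 and -0.026 with the replicate block, and the unfolded protein response in DIO against Lean to -0.015 within slide 2. Without DIO 1 and 6 the type II list turned to 0.038 in DIO against Lean and -0.093 in DIO-R against DIO, and gland markers in the latter to 0.049.

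Slide 3 turned the most. In DIO-R against DIO its values were -0.14 for type II, -0.16 for bitter, -0.082 for type III, -0.22 for type I, -0.12 for taste bud renewal, -0.0084 for basal keratinocyte, 0.075 for respiratory chain, 0.25 for muscle and 0.13 for adipocyte genes. In DIO-R against Lean they were -0.051 for taste bud renewal, -0.081 for immediate early, -0.0055 for basal keratinocyte, 0.196 for respiratory chain, 0.0296 for gland, 0.74 for muscle and 0.31 for adipocyte genes, and in DIO against Lean 0.11 for type II. DIO 1 and DIO 6, the DIO samples lowest in taste cell lists, lie on slides 1 and 2. For the taste lists, slide 3 and the fit without DIO 1 and 6 are therefore not separate checks. The cause of the other turns was not tested.

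The scan date was not run apart from the slide, with which it is identical. Scalings moved the median of all genes by less than 0.1. Signal over background limits dim genes such as Terb1, whose fold is a lower bound.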

Other observations

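The gene families given here were chosen after their values were seen, among 9 looked at, as was the choice of these tests.

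Of 12 acyl-CoA thioesterase genes measured, 9 were lower in DIO-R than in DIO, and the fall was uneven. Acot1 and Acot5 passed (-1.24 ± 0.13 SE and -1.28 ± 0.17 SE), Acot2 differed by -0.88 ± 0.19 SE (adjusted p = 0.0965) and Acot4 by -0.40 ± 0.18 SE (adjusted p = 0.502), while Acot8 and Acot9 differed by 0.16 ± 0.11 SE and 0.09 ± 0.07 SE. In DIO-R against Lean, genes outside the naming rule that passed included Ciart, a clock repressor (2.38 ± 0.35 SE, adjusted p = 0.00236), and the clock repressor Cry2 (0.43 ± 0.08 SE, adjusted p = 0.0338).

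All 5 genes of the late cornified envelope group 3 were lower in DIO than in Lean, with a median of -1.16, and none passed. The probes of the chemokine Ccl21 copies Gm13304 and Gm1987 were higher in DIO by 1.03 ± 0.22 SE and 1.24 ± 0.26 SE (both adjusted p = 0.11), and as near-identical copies they can share probe signal. Of 7 haemoglobin genes 6 were higher in DIO than in Lean, with a median of 1.20. Of 29 sweet, umami and bitter receptor genes 25 were higher in DIO-R than in DIO, with a median of 0.27 and none past the threshold. The bitter and type II lists, which cover such receptors, lay at 0.02 and -0.09 without DIO 1 and 6, the DIO samples lowest in taste cell lists. Within slide 3, which holds neither of these samples, those lists lay at -0.16 and -0.14. The tally is thus no separate evidence of a rise. Cxcl13, a chemokine that attracts B cells, differed by -2.28 ± 0.47 SE in DIO-R against Lean (adjusted p = 0.0584), and the fat cell hormone Adipoq differed by -1.75 ± 0.87 SE in DIO-R against DIO (adjusted p = 0.517).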
